A study of Homo sapiens with 6 samples.

How the data were processed

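RNA from THP-1 cells, a human monocytic leukaemia line, was measured on 6 single-colour oligonucleotide arrays with 31741 probes each. Per the labels' protocols, cells were pretreated with the vehicle DMSO or with 10 µM PBHA, stimulated with LPS at 50 ng/ml or left without it, and lysed 8 hours later. Column-purified RNA was amplified with an amino allyl kit and labelled with Cy5. The scanner, the image software and the authors' normalisation method are not given in the sources used here. Groups were taken from the treatment label of each sample, which gave 2 arrays with DMSO alone, 2 with DMSO and LPS, and 2 with PBHA and LPS. Replicate numbers follow the order of the samples, are not in the labels, and pair no arrays.

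The main input was the raw intensity per probe and array that the authors deposited, named so per the file headers. Its values were whole numbers from -2 to 65517, and as such values include negative ones, the background was taken as already subtracted, and no further background correction was applied. The correction planned for uncorrected values, normexp with an offset of 50, was therefore run only as an alternative. The deposited table also gave a detection p-value and a quality flag per probe and array. A second deposited table held the same raw intensities in all 190446 cells. The authors' normalized table held 1 intensity per group, a pooled value with no spread, together with log2 ratios between groups and a p-value for each. Those log2 ratios were the authors' own and were used only to set their calls beside the ones computed here.

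Intensities were quantile normalised between the 6 arrays, values under 1 were set to 1, and log2 was taken. Probes with a detection p-value under 0.05 on at least 2 of the 6 arrays were kept, which left 11571 of 31741. Symbols came from the deposited annotation and were updated through the Entrez gene number with a RefSeq gene table of assembly GRCh38.p14, used only for names. Of the probes, 25684 had 1 symbol, 1169 had several, 1868 had none, and 3020 were listed as probes of an earlier design without a symbol. The gene table held 25409 of the 1-symbol probes and changed the symbol of 2345. A gene was represented by its kept probe with the highest mean log2 level, giving 8551 genes, of which 1603 had more than 1 kept probe. In those, no probe of a gene called for LPS or for PBHA was called in the opposite direction, and for PBHA with LPS against resting 2 of 380 called genes had such a probe. No coordinates are given, because the files name no genome build.

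Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), fitting all 6 arrays in one model with a shared spread, 3 residual degrees of freedom and 2.43 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Means are of normalised intensities with the SD over the 2 arrays, and folds come from the log2 means. Where a gene was not detected on any array of a group, the fold is a bound, written "at least N-fold". It sets the bright group's mean against the mean of, per array, the higher of the lowest detected intensity and the dim probe's own. The lowest detected normalised intensity was between 313 and 393 on the 6 arrays.

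Before the data were examined, 36 gene lists were fixed, and lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01. The test was repeated with an estimated correlation, and adjusted p-values cover the 31 lists tested per comparison. The estimate was -0.093 for chemokines, -0.085 for cytokines and -0.0094 for interferon-stimulated genes, below the preset 0.01. The repeat takes its p-values with the 3 residual degrees of freedom of the arrays, and the preset test with degrees of freedom from the number of genes. For such lists the larger p-values of the repeat go with its fewer degrees of freedom, not with a stronger correlation between genes. Other lists had estimates above 0.01, such as 0.22 for the inhibitors of cytokine signalling. The rule for named genes was also fixed then. For each comparison it took the 6 largest rises and 6 largest falls, by the fitted change, among called genes whose groups do not overlap. Open reading frames, clone names, provisional symbols, Y-linked genes and X-inactivation genes were left out. It also took up to 3 called members of each list by size of change, or at most 2 of the brightest members where none was called, and always TNF, IL1B, IL6 and CXCL8. Some genes that this rule takes are not reported here.

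The method was first tested on simulated arrays made from the probes' own means and spreads. A seeded set of the brighter kept probes was changed between the resting and LPS groups. Noise was drawn independently for each probe, so a difference shared by arrays of all groups was not simulated. The rates below hold only for such probes and noise. Of 66 probes changed by 0.5, 67 changed by 1 and 67 changed by 2 on the log2 scale, 39.4%, 89.6% and 95.5% were called among 11571 probes, and 5.66% of calls were of unchanged probes. Comparisons that share the vehicle with LPS arrays were set beside 100 simulations of unchanged groups. Alternatives covered scaling to the 75th percentile or the median, an offset of 16, other filters on dim probes, fits of only the groups compared, an intensity trend, a minimum change, the mean over a gene's probes, and leaving out each array. Cyclic loess, the offset of 50, and a block for a difference shared by arrays of all groups were added after the data were seen. Tables and plots were made with pandas 2.3.3 and matplotlib 3.10.9.

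Detection, which sets what these arrays can show, was reached by 32.9% to 36.1% of probes per array. Between 18 and 70 probes per array lay at or above an intensity of 65000, where the scanner saturates. The number of arrays limits the precision.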

Results

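Expression was measured in THP-1 cells, a human monocytic leukaemia line, under 3 treatments with 2 arrays each. Cells received DMSO alone (resting), DMSO and the bacterial cell wall component LPS at 50 ng/ml, or PBHA at 10 µM and LPS at 50 ng/ml. RNA was taken after 8 hours. The comparisons ask which genes LPS changed and how PBHA pretreatment altered expression under LPS. The arrays detected between 10430 and 11459 of 31741 probes. Correlations between the 2 arrays of a group, across kept probes, were 0.986 for resting cells, 0.992 for vehicle with LPS and 0.988 for PBHA with LPS. The differences between the 2 arrays of a group were shared by the groups, correlating across probes at 0.770 between resting and vehicle with LPS arrays and at -0.817 between resting and PBHA with LPS arrays, which puts 1 array of each group on either side. The labels do not say that arrays came from separate cultures, so p-values of single genes measure only the spread between these arrays, which may be technical. P-values of lists at the preset correlation set a list's genes against the other genes and treat genes as nearly independent. Their size does not measure the spread between arrays.

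LPS raised 34 of 35 measured interferon-stimulated genes, 17 of 20 NF-kB targets and feedback genes, 7 of 9 chemokines and 6 of 10 cytokines. These lists held 38, 24, 22 and 23 genes, and the other members had no kept probe with 1 symbol. Probes detected only with LPS were kept, so genes that LPS raises are more likely to be measured. The shares do not hold for whole lists. With an estimated correlation between genes, a test with only 3 degrees of freedom, the chemokine and cytokine lists did not pass (adjusted p = 0.0688 and 0.0952). CXCL10, an interferon-inducible chemokine that attracts T cells, had a normalised intensity of 18883 ± 1090 (SD, n = 2) with LPS. It was not detected in resting cells at 279 ± 6.84, and was at least 57.4-fold higher (adjusted p = 2.82e-05). CCL2, a chemoattractant of monocytes, rose 22.2-fold, from 596 ± 3.12 to 13241 ± 319 (adjusted p = 2.24e-05). TNF rose 10.2-fold, from 598 ± 4.42 to 6128 ± 254 (adjusted p = 7.11e-05). IL1B was at least 7.02-fold higher, and CXCL8, a neutrophil chemoattractant detected on 1 of 2 resting arrays, was 6.79-fold higher. IL6, which had 1 probe, was not detected on any of the 6 arrays, where its raw intensity lay between 3 and 6. That is far below the raw medians of all probes, 109 to 152, so this probe does not show whether IL6 was expressed.

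In all, 1219 of 8551 genes passed the threshold between LPS and resting cells (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 598 were higher with LPS and 621 were lower. By the fitted change, 193 of the rises and 47 of the falls were at least 2-fold. These counts do not use bounds, so they include genes undetected in a group whose bound is under 2-fold. With scaling to the median, the median log2 fold change of all kept probes was -0.11, against -0.04 with quantiles. That scaling gave 468 higher and 742 lower genes, or 38.7% higher against 49.1%. Among genes higher with LPS, VCAM1, an adhesion molecule for leukocytes, was at least 5.43-fold higher. The interferon-inducible chemokine CXCL11 was at least 18.1-fold higher, IGFBP3, a carrier of insulin-like growth factors, at least 18.0-fold, and TNFAIP6, a secreted hyaluronan-binding protein, at least 3.15-fold.

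The interferon-stimulated genes rose together, with 34 of 35 measured members called and a median log2 fold change of 1.69. All 35 were called when adjusted over the list alone, and the list passed camera (adjusted p = 2.01e-36). OAS3, an oligoadenylate synthetase of the antiviral response, rose 5.39-fold, and IFIT1, which binds viral RNA, rose 5.01-fold. The exonuclease ISG20 was at least 5.01-fold higher. Of 20 measured NF-kB targets and feedback genes, 17 rose and 3 did not pass, with 18 called when adjusted over the list alone (median 1.64, adjusted p = 9.01e-21). ICAM1, a ligand of leukocyte integrins, was at least 5.49-fold higher and BCL3, an atypical member of the IkB family, at least 3.81-fold. These were the only lists past the threshold with an estimated correlation, at adjusted p = 0.0201 for the interferon-stimulated genes and 0.0283 for the NF-kB targets.

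Of 9 measured chemokines, 7 rose and 2 did not pass, or 8 rose when adjusted over the list alone (median 2.29, adjusted p = 9.44e-10, and adjusted p = 0.0688 with an estimated correlation). Among 10 measured cytokines 6 rose, also when adjusted over the list alone, and 4 did not pass (median 1.05, adjusted p = 1.04e-05, and adjusted p = 0.0952 with an estimated correlation). They included EBI3, a subunit of heterodimeric cytokines, which was at least 1.52-fold higher. With genes undetected in a group set at their bound, the medians were 1.97 for chemokines, 0.77 for cytokines, 1.55 for NF-kB targets and 1.66 for interferon-stimulated genes.

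**Figure D1:**
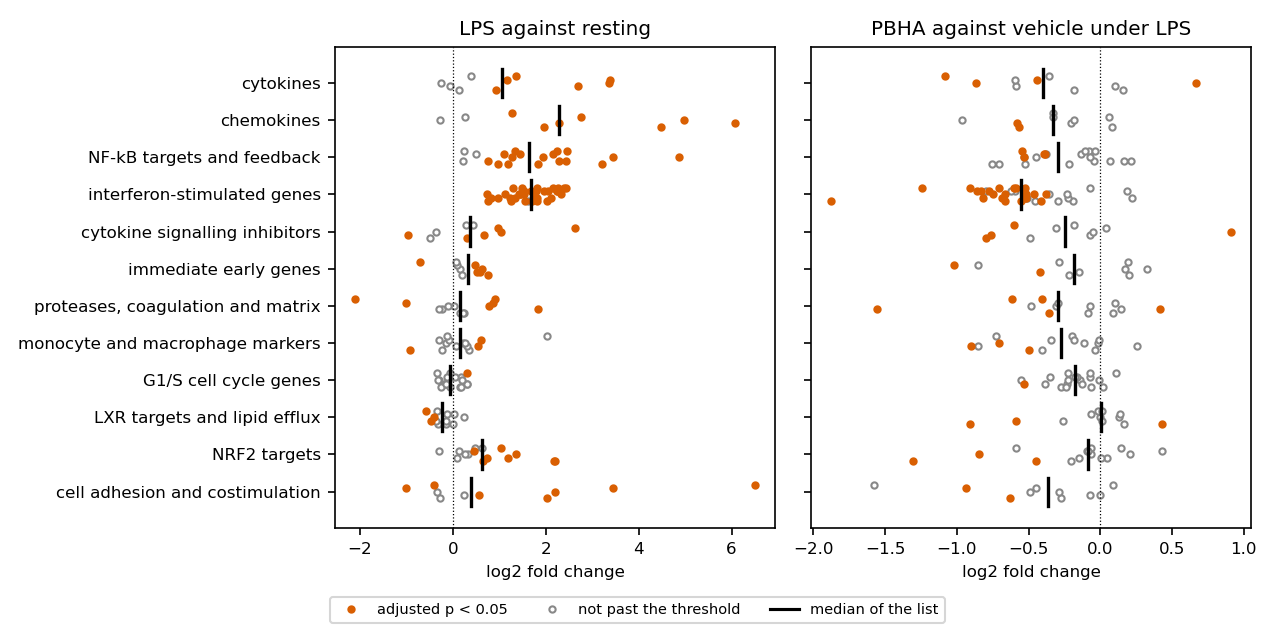
Log2 fold changes (horizontal axes) of the measured members of the 12 gene lists that passed camera in at least 1 of the 2 comparisons. Filled points are genes with adjusted p under 0.05, open points are the others, and black bars are list medians, such as 1.69 with LPS and -0.55 with PBHA for the interferon-stimulated genes.

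Of 15 measured NRF2 targets, genes of the oxidative stress response, 8 rose and 7 did not pass, with 10 called when adjusted over the list alone (median 0.62, adjusted p = 2.11e-07, and adjusted p = 0.0739 with an estimated correlation). FTH1, the ferritin heavy chain, rose 4.59-fold and OSGIN1 rose 2.56-fold, while HMOX1, a heme-degrading enzyme, was at least 2.51-fold higher. Among 10 inhibitors of cytokine signalling 5 rose, 1 fell and 4 did not pass, or 7 rose and 3 fell when adjusted over the list alone (median 0.36, adjusted p = 0.0181, and adjusted p = 0.558 with an estimated correlation). ZC3H12A, a ribonuclease that degrades cytokine messenger RNAs, rose 6.21-fold, and the MAP kinase phosphatase DUSP4 rose 2.04-fold. Of 10 immediate early genes 5 rose, 1 fell and 4 did not pass, with 5 and 1 called also when adjusted over the list alone (median 0.33, adjusted p = 0.00922, and adjusted p = 0.243 with an estimated correlation). ATF3 rose 1.69-fold and JUN 1.54-fold, and FOSL2 was at least 1.20-fold lower. ATF3 kept its call in 16 of 17 alternatives, JUN in only 7 of 17 and FOSL2 in 10 of 16.

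Genes lowered by LPS included SERPINB2, an inhibitor of plasminogen activators, which fell 4.30-fold from 10222 ± 292 to 2379 ± 82.1 (adjusted p = 0.00018). The calcium channel subunit gene CACNA2D3 fell 3.21-fold and the transcription factor gene NFE2 fell 2.96-fold. The mTOR inhibitor DEPTOR was at least 2.46-fold lower, the cannabinoid receptor CNR1 at least 1.5-fold and the histidine-degrading enzyme HAL at least 1.45-fold. LXR targets and lipid efflux genes were the only list past the threshold downward. Of 12 measured, 3 fell and 9 did not pass, or 6 fell when adjusted over the list alone (median -0.23, adjusted p = 0.0387, and adjusted p = 0.323 with an estimated correlation). These 3 were PLTP, which transfers phospholipids between lipoproteins (1.49-fold), MYLIP, which targets the LDL receptor for degradation (1.38-fold), and NR1H3, the gene of an LXR itself (1.32-fold). In this order they kept their call in 14, 12 and 9 of 17 alternatives. With the side of each array as a block, this list and the inhibitors of cytokine signalling did not pass (adjusted p = 0.0863 and 0.0538). The LXR list passed in 13 of 17 alternatives. Of 1640 called probes, leaving out resting_vehicle replicate 1 or 2 left a count of 599 or 771, leaving out vehicle_LPS replicate 1 or 2 left 506 or 465, and leaving out either PBHA_LPS array left 1049.

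**Figure D2:**
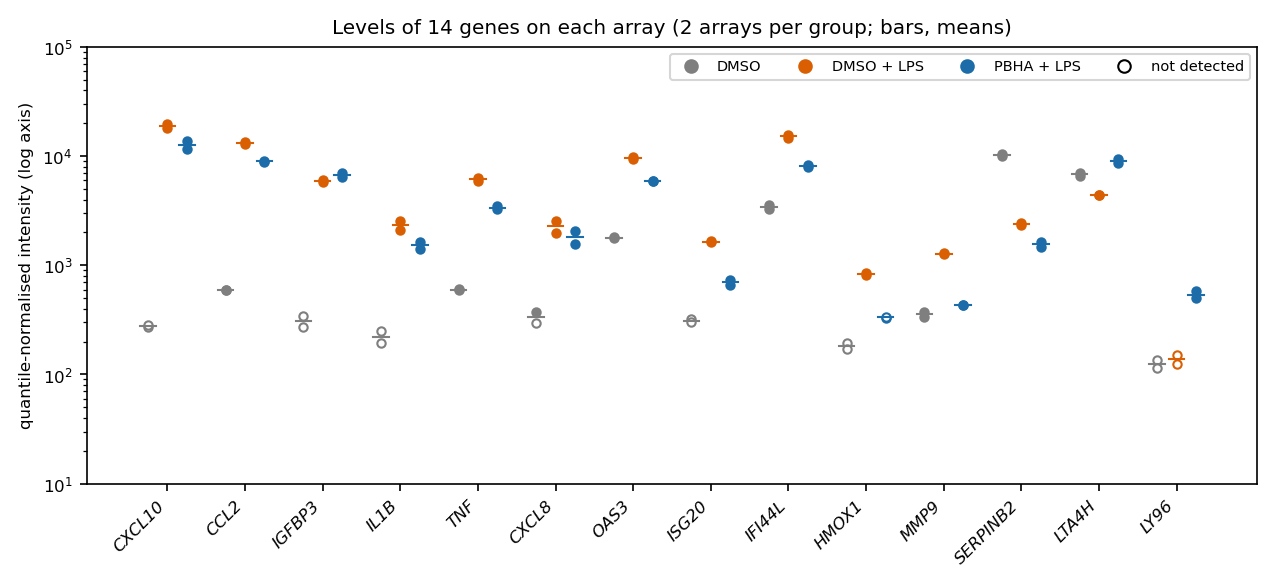
Quantile-normalised intensity (vertical log axis) of 14 named genes on each of the 6 arrays, by treatment. Points are arrays, open where the gene was not detected, and bars are the means of 2 arrays, such as 598, 6128 and 3369 for TNF in resting cells, with LPS, and with PBHA and LPS.

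Under LPS, PBHA lowered 22 of 35 measured interferon-stimulated genes, a list that did not pass with an estimated correlation (adjusted p = 0.0910). That test has only 3 degrees of freedom, and the estimate for this list was -0.0094, below the preset 0.01. TNF fell 1.82-fold, from 6128 ± 254 to 3369 ± 173 (SD, n = 2; adjusted p = 0.00558). MMP9, a matrix-degrading gelatinase, fell 2.95-fold, from 1278 ± 28.9 to 434 ± 2.36 (adjusted p = 0.00338). The interleukin-1 receptor antagonist gene IL1RN fell 2.12-fold from 6346 ± 912 to 2987 ± 276 (adjusted p = 0.0187). IL1B was at 1530 ± 148 with PBHA and 2318 ± 286 without (adjusted p = 0.0572), and CXCL8 at 1807 ± 352 and 2274 ± 414 (adjusted p = 0.32), so neither passed the threshold. With the side of each array as a block both did (adjusted p = 0.000144 and 0.0006). The sides were found from the same values, so these p-values may be too small, which was not tested. Without the block, the difference shared by the groups counts as spread, which can make p-values too large. Over 16 alternatives, that block among them, IL1B passed in 4 and CXCL8 in 1.

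Between PBHA and vehicle under LPS, 1556 genes passed, 845 higher with PBHA and 711 lower (limma, Benjamini-Hochberg). Of these, 59 rises and 34 falls were at least 2-fold by the fitted change, again without the use of bounds. With scaling to the median, the median log2 fold change of all kept probes was -0.16, against 0.00 with quantiles. That scaling gave 378 higher and 1399 lower genes, or 21.3% higher against 54.3%. Raw medians of all probes were 152 and 124 with PBHA and 119 and 109 with vehicle under LPS. They lay below the lowest detected raw intensities of the arrays, 326 to 409, so that scaling follows undetected probes. Leaving out vehicle_LPS replicate 1 or 2 gave 14 or 43 called probes against 2019, leaving out PBHA_LPS replicate 1 or 2 gave 292 or 82, and only 8 of 76 named genes kept their call when each array was left out.

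Of the 35 measured interferon-stimulated genes, 22 fell with PBHA, 13 did not pass, and 33 had a lower mean. Adjusted over the list alone, 28 fell. The median log2 fold change was -0.55, or -0.53 with bounds (adjusted p = 3.40e-13, and adjusted p = 0.0910 with an estimated correlation). ISG20 fell 2.37-fold, from 1649 ± 9.66 to 697 ± 43.4, and IFI44L fell 1.88-fold. The ubiquitin ligase gene HERC6, at 398 ± 5.54 without PBHA, was at least 1.11-fold lower.

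6 further lists passed camera downward, with fewer called members, and none of them passed with an estimated correlation. Of 20 NF-kB targets and feedback genes 4 fell and 16 did not pass, or 6 fell when adjusted over the list alone (median -0.30, adjusted p = 0.0193, and adjusted p = 0.386 with an estimated correlation). TNIP1, which restrains NF-kB signalling, fell 1.46-fold, TNFAIP6 fell 1.44-fold and the NF-kB inhibitor gene NFKBIE fell 1.31-fold. Of 9 chemokines 2 fell and 7 did not pass, or 4 fell when adjusted over the list alone (median -0.33, adjusted p = 0.0413, and adjusted p = 0.386 with an estimated correlation). These 2 were CXCL10, by 1.5-fold, and CCL2, by 1.48-fold. The chemokine list passed in 12 of 16 alternatives. Among 10 cytokines, a list that did not pass (adjusted p = 0.0827), 3 fell, 1 rose and 6 were not called, and IL18 rose 1.59-fold.

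Among 14 monocyte and macrophage markers 3 fell and 11 did not pass, or 5 fell when adjusted over the list alone (median -0.27, or -0.20 with bounds, adjusted p = 0.0193, and adjusted p = 0.386 with an estimated correlation). S100A8 and S100A9, the subunits of the calcium-binding protein calprotectin, fell 1.87-fold and 1.64-fold, and CSF1R, the receptor of a macrophage growth factor, fell 1.41-fold. Of 10 cell adhesion and costimulation genes 2 fell and 8 did not pass, or 4 fell when adjusted over the list alone (median -0.37, adjusted p = 0.0237, and adjusted p = 0.386 with an estimated correlation). The selectin ligand SELPLG was at least 1.40-fold lower and the integrin subunit ITGAL fell 1.55-fold. Of 13 protease, coagulation and matrix genes 4 fell, 1 rose and 8 did not pass, or 7 fell and 1 rose when adjusted over the list alone (median -0.29, adjusted p = 0.0413, and adjusted p = 0.539 with an estimated correlation). SERPINB2 fell 1.53-fold, with a log2 fold change of -0.62, or -0.43 as the mean over its probes, and kept its call in 12 of 17 alternatives. The metalloproteinase inhibitor TIMP2 rose 1.34-fold. This list passed in only 8 of 17 alternatives, and not with the side of each array as a block (adjusted p = 0.139). Among 19 G1/S cell cycle genes 17 had a lower mean, but only RRM2, a ribonucleotide reductase subunit, fell past the threshold, by 1.45-fold, and none did when adjusted over the list alone. The list median was -0.18 (adjusted p = 0.0176, and adjusted p = 0.386 with an estimated correlation).

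Genes higher with PBHA that were not detected on either array of vehicle with LPS included CLIC6, a protein of the chloride intracellular channel family (at least 2.76-fold), the laminin subunit LAMB1 (at least 2.62-fold) and the immunophilin FKBP1B (at least 2.13-fold). The desaturase SCD5 was at least 1.77-fold higher, the tight junction claudin CLDN10 at least 1.04-fold, and LY96, the partner of TLR4 that binds LPS, at least 1.44-fold. LTA4H, an enzyme of leukotriene synthesis, rose 2.06-fold, from 4393 ± 4.24 to 9053 ± 537 (adjusted p = 0.00493). Falls with PBHA included those of the receptor genes SLAMF8, by 3.70-fold, and GPR18, by 3.47-fold, and of the protease CTSO, by 2.91-fold, which was detected on 1 of 2 PBHA arrays. ACYP2, an acylphosphatase, was at least 2.31-fold lower.

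CXCL10, CCL2 and TNF, which PBHA lowered under LPS, were still higher than in resting cells. Against resting cells, PBHA with LPS gave 1138 higher and 1214 lower genes (limma, Benjamini-Hochberg). Of these, 189 and 101 changed at least 2-fold by the fitted change, without the use of bounds. With scaling to the median, the median log2 fold change of all kept probes was -0.24, against -0.01 with quantiles. That scaling gave 561 higher and 2925 lower genes, or 16.1% higher against 48.4%. CXCL10 was at least 38.4-fold higher than in resting cells, CCL2 15-fold and TNF 5.63-fold. GPR18 was 6.68-fold lower, SERPINB2 6.58-fold, CACNA2D3 4.61-fold, the exchange factor gene RASGRP2, detected on 1 of 2 PBHA arrays, 3.97-fold, and the nucleotide receptor gene P2RY2 3.49-fold. Of the interferon-stimulated genes 30 rose, 1 fell and 4 did not pass, or 34 rose and 1 fell when adjusted over the list alone (adjusted p = 3.37e-18, and adjusted p = 0.0567 with an estimated correlation). Of 20 NF-kB targets 16 rose, or 17 when adjusted over the list alone (adjusted p = 8.66e-13, and adjusted p = 0.0586 with an estimated correlation), among them TNFAIP3, an inhibitor of NF-kB signalling, by 5.66-fold. Of 9 chemokines 8 rose, or 8 rose and 1 fell when adjusted over the list alone (adjusted p = 1.95e-06, and adjusted p = 0.127 with an estimated correlation). Of 10 cytokines 6 rose by both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.000261, and adjusted p = 0.145 with an estimated correlation). Of 15 NRF2 targets 9 rose, also when adjusted over the list alone (adjusted p = 7.96e-05, and adjusted p = 0.140 with an estimated correlation). Of 9 eicosanoid enzymes and receptors 6 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0313, and adjusted p = 0.461 with an estimated correlation). That list passed in 12 of 17 alternatives, and its median was 0.07 with scaling to the median. The medians of these 6 lists were 1.13, 1.18, 2.08, 0.57, 0.51 and 0.37, or 1.07, 1.09, 2.05, 0.41, 0.48 and 0.30 with bounds. G1/S cell cycle genes passed downward (median -0.24), with 4 of 19 called, also when adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.461 with an estimated correlation), and passed in 14 of 17 alternatives. Of 3119 called probes, leaving out resting_vehicle replicate 1 or 2 left a count of 1483 or 1797, and leaving out PBHA_LPS replicate 1 or 2 left 1306 or 1332.

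**Figure D3:**
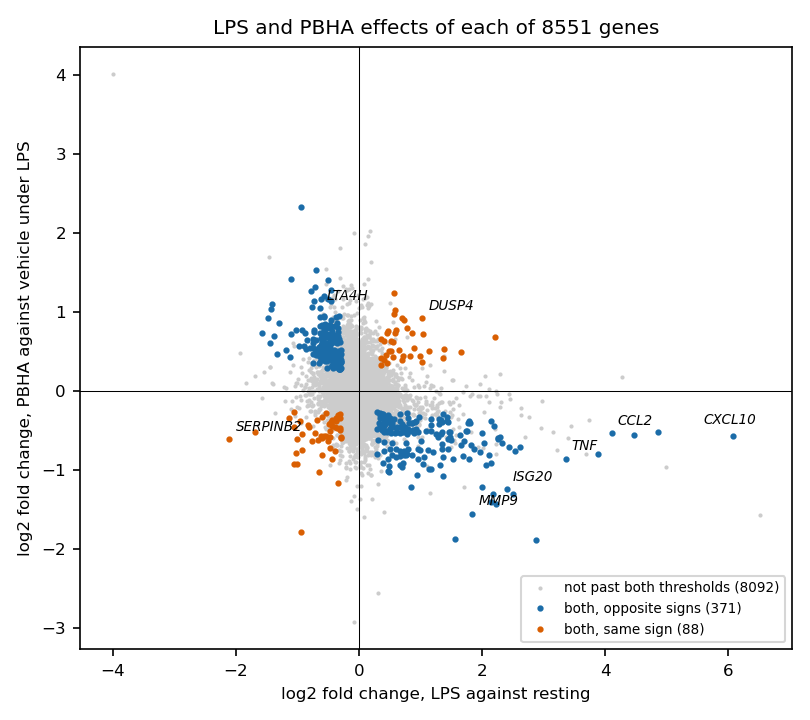
Log2 fold change with PBHA under LPS (vertical axis) against log2 fold change with LPS (horizontal axis), 1 point per gene. Blue points passed both thresholds with opposite signs, orange points passed both with the same sign, and grey points did not pass both; the correlation across genes was -0.324.

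More LPS-changed genes moved back with PBHA than further. Of 598 genes raised by LPS, 179 (29.9%) were lower with PBHA and 37 were higher, where independent lists would share 49.7 and 59.1. Of 621 genes lowered by LPS, 192 (30.9%) were higher with PBHA and 51 were lower, where independent lists would share 61.4 and 51.6. With scaling to the median, 241 raised genes were lower with PBHA and 20 higher, and 120 lowered genes were higher and 86 lower. With no filter on dim probes these counts were 52, 11, 47 and 5. Both comparisons use the vehicle with LPS arrays, whose chance values push the 2 effects apart. In 100 simulations of unchanged groups at most 1 gene was called in both with opposite signs, but such groups give almost no calls, so this does not measure how many shared calls come from the shared arrays. The correlation of the 2 effects was -0.324 across genes, which are not independent replicates, and the simulated median was -0.493. The covariance was -0.0464 against a simulated median of -0.0102, a difference of -0.0363. Of all genes 61.1% had opposite signs in the 2 effects, fewer than the simulated median of 66.6%. With a different vehicle array in each comparison, the covariance was -0.0373 or -0.0329. Each part then holds 1 array, and the 2 vehicle arrays lie on opposite sides of the difference shared by the groups. The split adds part of that difference to both effects with the same sign, so the move from -0.0464 does not measure chance from the shared arrays. The spread used in the simulations holds the shared difference too. Part of the excess of shared calls may come from the shared arrays. The count of genes raised by LPS and lower with PBHA was 99 or 108 without resting_vehicle replicate 1 or 2, 4 or 9 without vehicle_LPS replicate 1 or 2, and 32 or 12 without PBHA_LPS replicate 1 or 2. That of genes lowered by LPS and higher with PBHA was 31 or 68, 1 or 2, and 31 or 9 without the same arrays.

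The authors' deposited table lists probes with a log2 ratio of at least 1 in size. In the authors' deposited table, 164 ratios for PBHA and 382 for LPS had that size with p under 0.05. For PBHA against vehicle under LPS, the authors' deposited table gives 99 probes as higher and 65 as lower. For LPS against resting, the authors' deposited table gives 321 probes as higher with LPS and 62 as lower. Of these 321 in the authors' deposited table, 275 were kept here and 268 were called higher, and of the 62, all 51 kept were called lower. Among the 99 and 65 probes of the authors' deposited table, 63 and 47 were kept, and 62 and 44 were called in the same direction. Both sets of calls come from the same 6 arrays. Across probes, their log2 changes correlated at 0.994 for PBHA and 0.993 for LPS, so the shared calls are no independent check.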

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

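Cyclic loess, normexp with an offset of 50 and the array block were chosen after seeing the data; the other alternatives were set before the data were examined. The series-level table was not run because its values equal the raw ones, nor was the authors' normalized table, which has 1 value per group. The labels pair no arrays across groups, so no fit was paired by label. No called list or named gene changed direction under any alternative. Of 71 named genes called for LPS, 61 kept their call under the other scalings and 39 when each array was left out, and of 76 for PBHA, 62 and 8 did. Of 8 lists called for LPS, 8 and 7 did, and of 7 for PBHA, 5 and 5. With an estimated correlation between genes, 2 lists passed for LPS, 0 for PBHA and 0 for PBHA with LPS against resting; with only probes detected on all 6 arrays, 3 passed for PBHA. The raw median of all probes lay below the lowest detected intensity on each array, so scaling to the median follows undetected probes. Scaling to the median gave 378 higher and 1399 lower genes with PBHA, and 4681 probes, 561 higher and 2925 lower genes for PBHA with LPS against resting. It gave 120 genes lowered by LPS and higher with PBHA, 20 higher with both, and 86 lower with both. With no filter on dim probes, 1020 probes and 232 lower genes passed for LPS, 838 probes, 381 higher and 224 lower genes for PBHA, and 807 lower genes for PBHA with LPS against resting. The genes changed by both were then 52 raised and lowered, 47 lowered and raised, 11 raised by both and 5 lowered by both, and the correlation of the effects was -0.421. Fits of only the groups compared, which have fewer arrays, gave 1049 probes and 344 lower genes for LPS and 806 lower genes for PBHA with LPS against resting. A log2 fold change of at least 1 leaves fewer calls by construction: 318 probes, 193 higher and 47 lower genes for LPS, 110, 59 and 34 for PBHA, and 379, 189 and 101 for PBHA with LPS against resting, with 10, 3, 0 and 0 genes changed by both in the order above. The array block gave 6637 probes, 2013 higher and 2889 lower genes for LPS, 7111, 2734 and 2548 for PBHA, and 7643, 2733 and 2923 for PBHA with LPS against resting, with 992, 1299, 342 and 602 genes changed by both. All 1640, 2019 and 3119 probes called without the block were among these in the same direction. The block was found from the same values, so its p-values may be too small, which was not tested. Without it the difference shared by the groups counts as spread, which can make p-values too large. With the block IL1B and CXCL8 passed for PBHA, and 2 lists for LPS and 1 for PBHA lost their call. With different vehicle arrays in the 2 effects, their correlation was -0.242 or -0.213, a split that also adds part of the difference between the array sides to both effects. Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 465 to 1049 probes for LPS (253 to 443 genes higher, 93 to 344 lower), 14 to 1495 for PBHA (5 to 609 higher, 5 to 535 lower) and 1306 to 2124 for PBHA with LPS against resting (473 to 791 higher, 427 to 807 lower). The genes changed by both numbered 4 to 108, 1 to 68, 0 to 17 and 0 to 16, the correlation lay between -0.412 and -0.256, and 8 to 10, 6 to 8 and 6 to 7 lists passed. Without a filter on dim probes, p-values were adjusted over 31741 probes and not 11571, and the array block takes the shared difference out of the spread. Leaving out 1 array of a compared group leaves that group on 1 side, so part of the shared difference enters the change. Apart from these points, the fewer arrays and the stricter threshold, causes were not tested, nor was the part of each point. Fold values of genes not detected on any array of a group are bounds.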

Other observations

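The covariance test of opposing effects and the 2 checks on the share of the LPS rise lost were chosen after the result was seen, as were the raw values of the single probes given here. Several gene groups outside the lists described moved in part. Among 15 apoptosis regulators, LPS lowered BCL2, an inhibitor of apoptosis, 2.21-fold and raised the pro-apoptotic genes BID (1.82-fold) and PMAIP1 (1.41-fold). With PBHA under LPS, BID fell 1.33-fold, PMAIP1 fell 1.40-fold and CASP8, an initiator caspase, rose 1.44-fold. In this order they kept that call in 12, 11 and 12 of 17 alternatives, and PMAIP1 kept its LPS call in only 9 of 17. BTG2, an antiproliferative p53 target, rose 6.20-fold with LPS. KIT, a receptor of immature blood cells, fell 2.03-fold with LPS, as did GFI1, a repressor of myeloid genes, by 1.45-fold. IDO1, which degrades tryptophan, was at least 1.85-fold higher with LPS and fell 1.45-fold with PBHA. Its call for PBHA was kept in only 8 of 16 alternatives. None of the lists these genes come from passed camera in those comparisons.

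With PBHA, 3 of 18 measured cholesterol synthesis and uptake genes rose and none fell, among them SQLE (1.36-fold) and LSS (1.23-fold). SQLE kept its call in only 10 of 17 alternatives and LSS in 7 of 17. The list did not pass camera (adjusted p = 0.241). HK1, a hexokinase of glycolysis, rose 1.70-fold. Of 15 NRF2 targets 3 fell, or 3 fell and 1 rose when adjusted over the list alone, with HMOX1 at least 2.29-fold lower, OSGIN1 1.80-fold and FTH1 1.37-fold. That list did not pass camera either (adjusted p = 0.174, and adjusted p = 0.483 with an estimated correlation). The immediate early gene FOS fell 2.03-fold and EGR1 1.34-fold. Of 9 measured histone deacetylase genes only HDAC11, detected on 1 of 2 arrays of vehicle with LPS, was called, 1.47-fold higher. Of the markers of other cell types, 4 lymphocyte genes, 2 stromal or endothelial genes and no epithelial gene were among the kept probes. The lymphocyte gene CD79B fell 1.26-fold with LPS and rose 1.68-fold with PBHA, and NKG7 fell 1.49-fold with PBHA. CD79B kept its call in only 5 of 17 alternatives for LPS and in 14 of 17 for PBHA, and NKG7 in 9 of 17.

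SERPINB2 is known as a gene that LPS raises in monocytes, and here both of its probes were dimmer with LPS. Raw intensities were 11160 and 12575 on the resting arrays and 2332 and 1974 with LPS for 1 probe, and 10194, 11058, 1513 and 1306 for the other. With PBHA this other probe read 1442 and 1161. A single probe that the annotation assigns to several genes read 841 and 958 on the resting arrays, -1 and 0 on the vehicle with LPS arrays, and 873 and 788 with PBHA, with a quality flag on both vehicle with LPS arrays.

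Differences between the 2 arrays of a group were shared by the 3 groups. Across kept probes, the difference of replicate 1 and 2 in resting cells correlated with that in vehicle with LPS at 0.770, and with that in PBHA with LPS at -0.817. After a loess trend on the mean level was removed the smallest of these correlations in size was still 0.771, which argues against a bias with signal level left by the scaling. The shared difference of a gene's 2 probes correlated at only 0.0963 (bootstrap interval 0.0409 to 0.153) over 1603 genes, against 0.794 for the LPS effect and 0.684 for the PBHA effect. This argues against a difference in the RNA or the cells that moves the probes of a gene alike. A difference in the RNA that moves them unequally would also give a low correlation and was not tested. A probe-level difference in hybridisation or scanning between sets of arrays is a candidate explanation that these values leave open, as a hypothesis.

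The opposing effects of LPS and PBHA across genes could come from chance values of the shared vehicle with LPS arrays. The covariance of -0.0464 lay below the lowest of 100 simulations, -0.0191. The simulations drew each gene independently, with the spread between the arrays of a group. The covariance therefore argues only against independent chance values of that size as the whole cause. A deviation common to both vehicle with LPS arrays was not simulated, so the simulations cannot decide on it. The share of genes with opposite signs, 61.1%, was below the simulated median of 66.6%, so the signs alone do not show opposing effects beyond the simulated ones. Whether PBHA acts on the response to LPS or on the same genes without it stays open, since no sample used here received PBHA without LPS.

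A hypothesis set before its test was that interferon-stimulated genes lose a larger share of their LPS rise with PBHA than NF-kB targets, cytokines and chemokines. On the log2 scale, 34 interferon-stimulated genes raised by LPS lost a median of 35.5% and 30 genes of the other lists 17.8%, a difference of 17.8 percentage points (permutation test, two-sided, p = 0.00066). All 598 genes raised by LPS lost a median of 26.8% (quartiles 4.35% and 52.9%), which lies between the 2. On linear intensities the medians were 48.2% and 32.6% (permutation p = 0.00747). With only genes detected on both resting arrays, 28 and 15 genes, the medians were 34.1% and 25.7%, a difference of 8.35 points (permutation p = 0.27), so the hypothesis was not decided. These permutations treat genes as independent, so their p-values do not measure the spread between arrays. Each share uses the vehicle with LPS arrays for both effects, in genes called higher on them, which pushes shares toward a loss. A further hypothesis, that genes often raised by histone deacetylase inhibitors are higher with PBHA, was not decided either. Of 7 measured, 3 rose, among them ENO2 (1.44-fold) and CDKN1A (1.27-fold), and none fell, or 3 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 0.016 (camera adjusted p = 0.657). ENO2 kept its call in 12 of 17 alternatives, and CDKN1A in only 5 of 17.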
